A study of Homo sapiens with 6 samples.

How the data were processed

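RNA sequencing measured messenger RNA in 6 libraries of HaCaT, a spontaneously immortalised human keratinocyte line. Per the labels' protocols, the cells received lentivirus with a scrambled shRNA (control, 3 libraries) or an shRNA against NCSTN (knockdown, 3 libraries). Puromycin at 2 mg/L was applied for 5 days from 72 h after infection, per the labels' protocols, and RNA was then taken. Per the labels' protocols, mRNA was captured on poly-T beads, fragmented, copied from random hexamers and read as pairs of 150 bp. A capture on poly-T beads under-represents RNA without a poly(A) tail. The labels do not say whether strand was kept, so reads of a gene and of an overlapping antisense gene cannot be told apart here. Nothing in the labels says that the 3 libraries of a group came from separate infections or cultures, and p-values then measure only the spread between these libraries, which may be technical. No second shRNA against NCSTN and no rescue was analysed here, so differences between the groups include any off-target effect of the shRNA.

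The deposited expression table held 1 FPKM value per gene and library (fragments scaled by gene length and library depth), with no replicates pooled. A second deposited table held the authors' own comparison. Per the file headers it gave a mean read count per group, which was not a whole number and was treated as a normalised signal. The log2 fold change in that table was, by the deposited values, the log2 of the ratio of those means to within 5e-05. The p-value and adjusted p-value there came from a test that the file headers do not name, and only genes with an adjusted p of at most 0.0499 were listed by the authors. In 14 cells the authors' fold change read as infinite, and in 153 cells, all with a knockdown mean of 0, it held a spreadsheet error. Per the submitters' processing notes, fastp and edgeR were used, with no version or role given, and the build listed there is the mouse build mm10, although the gene identifiers are those of human Ensembl genes. The aligner, the counter and the human annotation are not given in the sources used here.

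The expression table listed 48162 genes, of which 16996 were at 0 in every library. A reference table of gene names matched 45038 identifiers, the authors' table named 277 more, and 2847 had no symbol. Positions, gene types, lengths and GC content came from GENCODE release 29 on GRCh38, which held 45342 of the identifiers. It is not known to be the annotation that the authors used.

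No raw counts were used here, so the test was the one fixed for FPKM: limma 3.58.1 in R 4.3.3 with a variance trend and robust empirical Bayes on log2(FPKM + 1). It was run on the 13615 genes with a mean FPKM over all libraries of at least 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. A limit of 2-fold, a log2 change of 1, was applied beside it. Gene lists were compared with the other tested genes by camera with a preset inter-gene correlation of 0.01 and with the correlation estimated per list. The fry test, which asks whether a list moves on balance one way and does not compare it with other genes, was run beside it. Of 35 lists fixed before the data were examined, 31 had at least 5 measured members and were tested, with adjustment over those lists. They covered gamma-secretase, Notch, keratinocyte layers, immunity, growth, metabolism, stress and markers of other cell types.

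Low FPKM values are whole multiples of what 1 read is worth for the gene. Comparing low genes between libraries gave the relative depth, and the smallest whole numbers in the right ratio gave reads for 100% of the 31166 genes above 0, with a tolerance of 0.003 reads. For 2.22% of the genes the authors listed, their means showed that the reads were a multiple of the smallest solution, and that multiple was used. On simulated genes 98.18% were recovered exactly. Recovered reads summed to between 20319637 and 23291081 per library. They served to judge depth and as an added alternative, limma voom with median-ratio factors, chosen after the steps were seen.

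The genes named are the gamma-secretase subunits, the 12 genes with the largest rise and the 12 with the largest fall among symbol-named genes past the threshold whose groups did not overlap, and in each list up to 4 members with the smallest adjusted p. Where no member of a list passed, up to 2 members with the highest FPKM were to be named. This rule, the test and the alternatives were set before the data were examined, and genes named outside it are said to be so. Some genes that the rule takes are not reported here. The alternatives changed the pseudocount, the low-value filter, the scaling between libraries, the variance model, the replicates and a block by replicate number. A removal of length and GC trends was added later, and 97.26% of the tested genes had both values. Tests that need raw counts were not run.

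The fit was tested on simulated data of the knockdown against control comparison with 200 of 13615 genes changed. It recovered 52% of genes changed 1.2-fold, 82% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 7.78% of its calls were false. Of 100 random lists of unchanged genes, 2 had a list p under 0.05. Genes were drawn independently of each other there, whereas the real lists had estimated correlations of up to 0.783. The simulation thus does not test the preset correlation on lists whose genes move together. It also changed a far smaller share of genes than the 71.7% that passed in the real data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.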

Results

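The data are 3 control and 3 knockdown libraries of HaCaT keratinocytes, compared to see which transcripts differ when NCSTN is silenced. NCSTN encodes nicastrin, a subunit of gamma-secretase, the membrane protease that cleaves Notch receptors and other single-pass membrane proteins. Reads recovered from the steps of the FPKM values came to 23291081, 20319637 and 20795780 in control libraries 1 to 3, and to 22250854, 21643356 and 22757784 in knockdown libraries 1 to 3. Genes above 0 numbered 24550, 24523 and 25713 in the control and 23659, 23556 and 23158 in the knockdown. Processed pseudogenes above 0 numbered 1966 to 2299 per control library and 1593 to 1769 per knockdown library. Pearson's r across genes lay between 0.9955 and 0.997 within groups and between 0.9364 and 0.9422 between them, where genes are not independent replicates. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.07 to 6.91, and each was counted as 1 sample. The median CV beyond counting noise was 3.36% in the control and 2.77% in the knockdown, and neither value shows that the libraries came from separate cultures.

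NCSTN mRNA (ENSG00000162736, chromosome 1, 160343272 to 160358952, plus strand, GRCh38) was lower in every knockdown library. It stood at 74.7, 74.6 and 74.9 FPKM in control libraries 1 to 3 and at 32.7, 34.3 and 35.0 in knockdown libraries 1 to 3. The knockdown mean was 45.6% of the control mean, a log2 fold change of -1.11 (SE 0.0463, limma adjusted p = 9.49e-11). An exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest it allows. Other subunits moved both ways. PSEN2, a catalytic subunit, fell from 12.2 ± 1.03 to 5.70 ± 0.0503 FPKM (SD, n = 3), while APH1A rose from 132.6 ± 2.32 to 164.4 ± 2.49. PSENEN was at 2.22 ± 0.546 and 2.89 ± 0.549 FPKM and did not pass (adjusted p = 0.087), and it passed without control library 2 (adjusted p = 0.0139, with a range of 0.0139 to 0.325 over its alternatives). APH1B fell from 2.25 ± 0.288 to 1.69 ± 0.0507 FPKM (adjusted p = 0.0421) on a mean of 52.0 and 40.3 reads, and it missed the threshold in 8 of 16 alternatives.

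**Figure D1:**
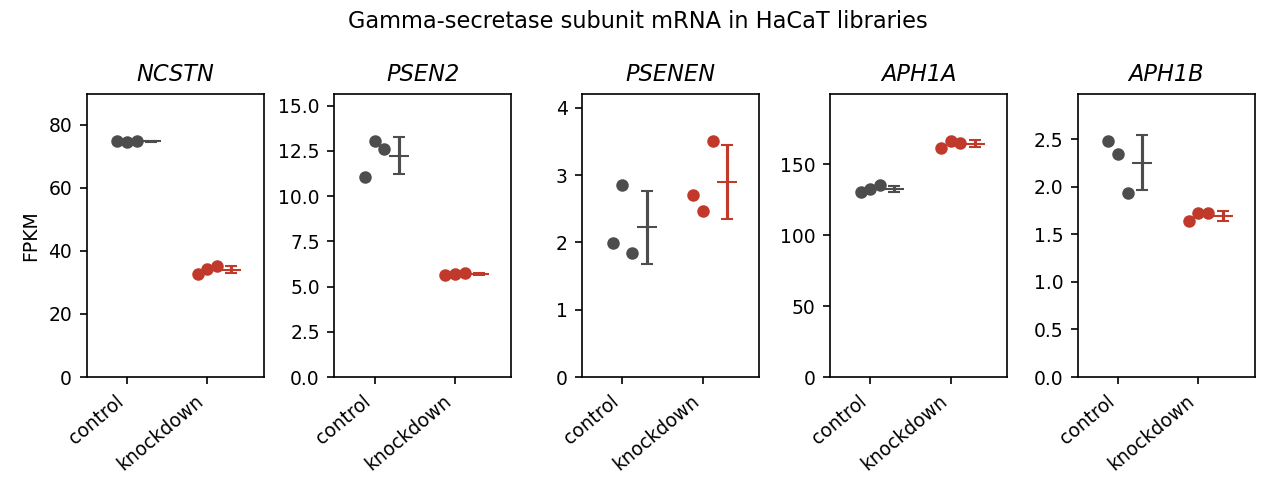
FPKM (vertical axes, each from 0) of 5 gamma-secretase subunits in control (grey) and knockdown (red) libraries, with 1 point per library and the mean with its SD beside the points. NCSTN sits between 74.6 and 74.9 FPKM in the control libraries and between 32.7 and 35.0 in the knockdown libraries.

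Across the transcriptome, the largest changes included falls of FOS, FOSB, THBS1 and FN1 and rises of MKI67 and TOP2A. FOS and FOSB, components of the AP-1 transcription factor, were 144.3-fold and 190.2-fold lower by mean FPKM. THBS1, which encodes the matrix protein thrombospondin 1, was 33.4-fold lower, and FN1, which encodes fibronectin, 24.4-fold lower. MKI67 and TOP2A, both used as markers of dividing cells, were 5.96-fold and 5.73-fold higher. Of 13615 tested genes, 9757 passed the threshold (71.7%), 5834 higher and 3923 lower in the knockdown. With libraries scaled to the same upper quartile, 4713 were higher and 4840 lower, so the balance of directions depends on the scaling. At least 2-fold changes were seen in 670 genes that rose and 775 that fell, against 553 and 913 with upper-quartile scaling and 806 and 1294 with recovered reads. The groups did not overlap for 74.3% of tested genes, where chance gives 10%. The median absolute log2 change was 0.338, and 2403 of the genes that passed had a change under 0.3.

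**Figure D2:**
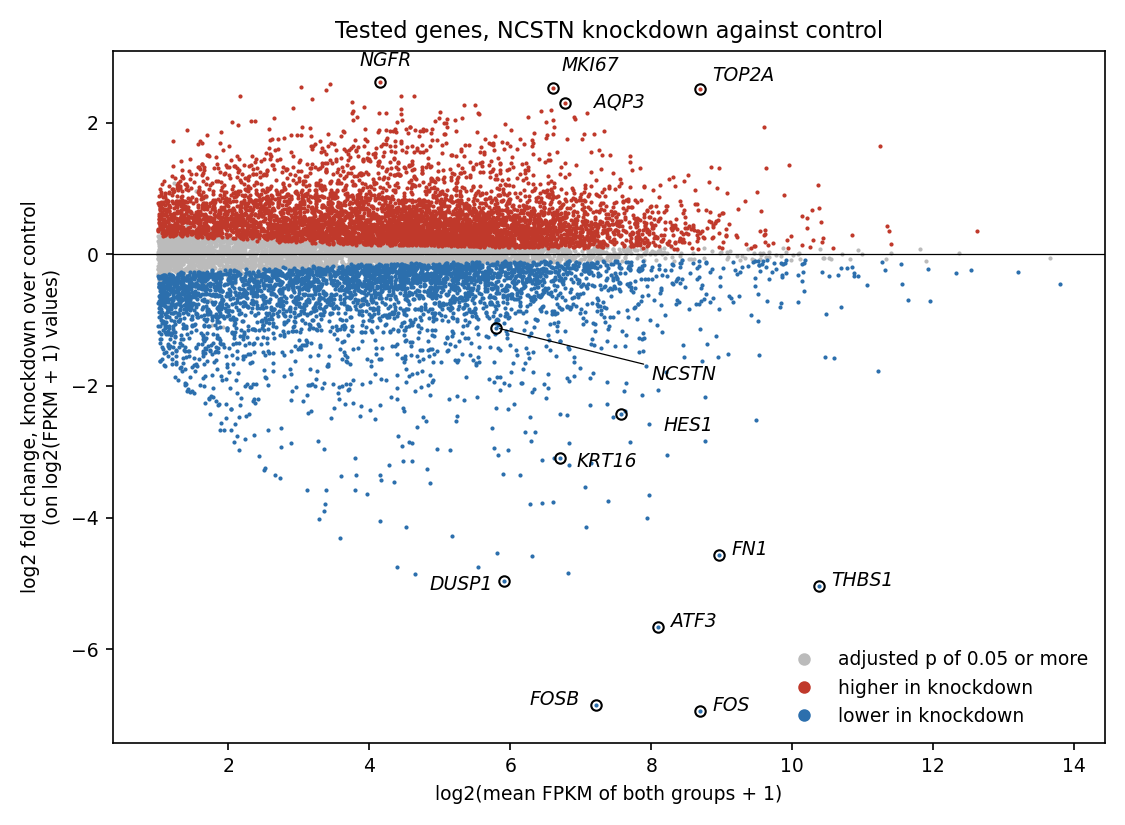
Log2 fold change of knockdown over control (vertical axis) against the log2 of the mean FPKM plus 1 (horizontal axis) for the 13615 tested genes, with 5834 higher genes in red, 3923 lower genes in blue and genes that did not pass in grey. FOS and FOSB lie lowest, at -6.95 and -6.86, and NGFR lies highest, at 2.62.

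On the log2(FPKM + 1) scale, the 12 largest falls were led by FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230), from 822 ± 18.1 to 5.70 ± 0.756 FPKM, and by FOSB, from 293 ± 9.19 to 1.54 ± 0.110, although the ratio of mean FPKM was larger for FOSB. ATF3, a stress-induced transcription factor, fell from 537 ± 2.72 to 9.63 ± 0.341 FPKM, and THBS1 (ENSG00000137801, chromosome 15, 39581079 to 39599466) from 2575 ± 27.2 to 77.1 ± 4.12. The others were DUSP1, PSG5, CCN1, RASD1, ADAMTS1, NR4A1, FN1 and PTGS2, with log2 changes between -4.97 and -4.54. PSG5 belongs to a family of near-identical genes, so its value is uncertain. On the same scale, the 12 largest rises were led by NGFR (ENSG00000064300, chromosome 17, 49495293 to 49515017), which encodes the low-affinity neurotrophin receptor, from 3.99 ± 0.513 to 29.6 ± 1.93 FPKM. SOX2 rose from 2.09 ± 0.232 to 17.6 ± 2.33 FPKM and CIITA, the master activator of MHC class II genes, from 2.13 ± 0.128 to 16.8 ± 2.13. AQP3, a water and glycerol channel of keratinocytes, rose from 36.0 ± 1.13 to 181.0 ± 9.85 FPKM. The others were LINC03080, MKI67, TOP2A, KNL1, MARCO, TP53I11, FOXN1 and ANKRD22. MARCO, at 0.418 ± 0.168 FPKM in the control and 6.52 ± 1.15 in the knockdown, had the lowest level of these and the largest ratio of mean FPKM, 15.6-fold against 7.41-fold for NGFR.

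Cell division genes were higher as a group. All 30 measured G2/M and mitosis genes rose, with a median log2 change of 1.94 (camera adjusted p = 7.93e-14, and adjusted p = 0.119 with an estimated correlation). MKI67 rose from 27.7 ± 0.751 to 165.0 ± 0.511 FPKM, TOP2A, a DNA topoisomerase, from 122 ± 6.82 to 701 ± 14.8, and CENPF, a kinetochore protein, from 30.5 ± 0.345 to 141 ± 1.74. Of 30 DNA replication genes, 29 rose and 1 fell, with a median of 1.19 (adjusted p = 1.02e-09, and adjusted p = 0.0953 with an estimated correlation). MCM6, a subunit of the replicative helicase, rose from 14.3 ± 0.721 to 63.5 ± 4.87 FPKM and RRM2, which makes deoxynucleotides, from 35.6 ± 2.02 to 121 ± 4.93. All 12 measured replication-dependent histone genes fell, with a median of -1.19 (adjusted p = 7.48e-07, and adjusted p = 0.119 with an estimated correlation), among them H2BC21 from 26.0 ± 0.558 to 4.21 ± 0.146 FPKM. Of the 33 listed histone genes only these 12 were measured. Replication-dependent histone transcripts mostly lack a poly(A) tail and their gene copies are near-identical, so their levels in these libraries are uncertain. Of 36 nuclear genes of oxidative phosphorylation, 35 rose and 1 fell, with a median of 0.75 (adjusted p = 2.76e-09, and adjusted p = 0.0741 with an estimated correlation), including ATP5F1A, an ATP synthase subunit, from 323 ± 9.5 to 653 ± 8.35 FPKM. Of the 13 mitochondrially encoded genes 5 rose and 5 fell, and the list did not pass (adjusted p = 0.528).

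Immediate early genes, which answer growth factors and stress within minutes, were lower as a group. Of 27 measured, 26 fell and 1, FOSL2, did not pass, with a median log2 change of -2.37 (camera adjusted p = 2.44e-17, and adjusted p = 0.0741 with an estimated correlation). Of 17 EGFR ligands, receptors and feedback genes, 14 fell and 2 rose (median -0.92, adjusted p = 5.32e-06, and adjusted p = 0.0684 with an estimated correlation), and the median was -0.52 with no filter on low values. HBEGF, an EGFR ligand, fell from 90.7 ± 2.03 to 13.8 ± 0.868 FPKM and DUSP6, a feedback phosphatase of ERK, from 141 ± 1.76 to 35.3 ± 0.770. Of 30 extracellular matrix and mesenchymal genes, 22 fell and 3 rose (median -1.07, adjusted p = 3.92e-09), and this call held with an estimated correlation (adjusted p = 0.0341). FN1 fell from 956 ± 6.80 to 39.1 ± 1.74 FPKM and INHBA, a subunit of activin, from 136 ± 5.52 to 18.2 ± 0.474. With no filter on low values the median of the matrix list was -0.38, with 21 of 38 genes that fell and 2 that rose. Of 15 fibroblast markers, 6 fell and 1 rose without a filter, and that list did not pass (adjusted p = 0.0708). Control library 2 stood apart on the fibroblast markers DCN, at 2.36 FPKM against 0.876 and 0.555 in the other control libraries, and COL3A1, at 2.44 against 0.832 and 0.693, both named after their values were seen. Without that library 22 matrix genes fell and 2 rose (adjusted p = 3.09e-09, with a range of 8.06e-11 to 1.94e-07 over its alternatives). Of 13 metalloproteinases and inhibitors, 10 fell and 3 rose (median -1.66, adjusted p = 1.27e-04, and adjusted p = 0.0741 with an estimated correlation). The median was -0.99 with no filter, and 1 rose with upper-quartile scaling. MMP10 fell from 67.8 ± 4.65 to 2.55 ± 0.262 FPKM, whereas MMP28 rose from 80.6 ± 5.32 to 231 ± 4.0. Of 13 Wnt target genes, 8 fell and 3 rose (adjusted p = 0.00209, and adjusted p = 0.119 with an estimated correlation), and DKK1, itself a Wnt inhibitor, fell from 462 ± 6.70 to 27.8 ± 1.86 FPKM. Some genes stand in several lists, such as CCN1 in the immediate early and matrix lists and MYC in the immediate early, Notch and Wnt lists.

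Notch target genes were mostly lower, and the pathway's own genes moved both ways. Of 17 measured targets, 10 fell and 3 rose (median -0.37, adjusted p = 0.0083, and adjusted p = 0.312 with an estimated correlation), and the median was -0.56 with recovered reads. HES1, the best-known direct target, fell from 321 ± 9.02 to 58.8 ± 2.82 FPKM, MYC from 329 ± 14.3 to 62.7 ± 3.58 and SOX9 from 95.5 ± 7.30 to 11.6 ± 0.521, while ID1, better known as a target of BMP signalling, rose from 286 ± 13.8 to 616 ± 24.7. HEY1, another direct target, named after its values were seen, stood at 6.59 and 6.64 FPKM and did not pass, and NRARP, a feedback inhibitor of Notch chosen likewise, rose from 22.7 to 39.9. Of 24 receptors, ligands and pathway genes, 10 rose and 10 fell (adjusted p = 0.298), and 6 rose and 13 fell with upper-quartile scaling. NOTCH3 rose from 20.2 ± 1.82 to 58.8 ± 3.43 FPKM, and the ligand DLL1 fell from 25.3 ± 1.75 to 7.76 ± 0.242. Of 21 other gamma-secretase substrates, 11 rose and 9 fell (adjusted p = 0.827), with the adhesion protein NECTIN1 up from 285 ± 12.1 to 712 ± 12.2 FPKM and CDH2, which encodes N-cadherin, down from 36.7 ± 1.42 to 6.24 ± 0.304.

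Keratinocyte genes moved both ways, and the lists were not tested against each other. Of 12 stress and follicular keratins, 9 fell and 2 rose (median -1.05, adjusted p = 6.70e-04, and adjusted p = 0.312 with an estimated correlation), and the median was -0.68 with no filter and -1.62 with recovered reads. KRT16 fell from 186 ± 12.1 to 20.8 ± 1.47 FPKM and KRT17 from 1217 ± 66.5 to 213 ± 14.4, both with near-identical relatives in the genome. Of 20 basal layer and hemidesmosome genes, 16 fell and 2 rose (median -0.28, adjusted p = 4.17e-04, and adjusted p = 0.119 with an estimated correlation). COL7A1, the anchoring fibril collagen, fell from 209 ± 14.6 to 79.7 ± 2.95 FPKM, whereas KRT15 rose from 858 ± 26.9 to 1789 ± 91.8. Of 27 cornified envelope and differentiation genes, 14 rose and 9 fell (adjusted p = 0.766). KRT13 rose from 1173 ± 42.1 to 3698 ± 285 FPKM, and IVL, which encodes involucrin, fell from 148 ± 3.92 to 58.9 ± 1.82. Of 24 desmosome and tight junction genes, 15 rose and 6 fell (adjusted p = 0.158), and the list passed without a filter on low values (adjusted p = 0.00491, with a range of 0.00491 to 0.257 over its alternatives). CGN, which encodes cingulin, rose from 26.6 ± 0.313 to 88.9 ± 2.12 FPKM.

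Interferon-stimulated genes were higher. Of 41 measured, 35 rose and 2 fell, with a median log2 change of 0.80 (camera adjusted p = 1.00e-06, and adjusted p = 0.263 with an estimated correlation). OAS3, an antiviral sensor of double-stranded RNA, rose from 48.9 ± 1.31 to 222 ± 7.97 FPKM, OAS1 from 11.5 ± 0.388 to 45.5 ± 3.29 and IFITM1 from 32.7 ± 0.820 to 81.4 ± 3.72. Of 15 MHC class I presentation genes, 12 rose and 1 fell (median 0.49, adjusted p = 0.00423, and adjusted p = 0.117 with an estimated correlation), with the immunoproteasome subunit PSMB9 up from 42.2 ± 2.60 to 107 ± 2.48 FPKM. The 4 immune cell markers above the filter also rose, namely CD74 from 13.2 ± 0.810 to 53.1 ± 3.76 FPKM, HLA-DRA from 2.25 ± 0.151 to 7.84 ± 0.584, CD14 from 1.47 ± 0.287 to 4.05 ± 0.932 and ITGAM from 0.964 ± 0.172 to 1.67 ± 0.366, and ITGAM missed the threshold without knockdown library 1 (adjusted p = 0.0525, with a range of 0.00249 to 0.0525 over its alternatives). Without a filter, 4 of 17 immune cell markers rose and 3 fell, and among those below it CSF1R stood at 1.15 ± 0.0835 FPKM in the control and 0.268 ± 0.0231 in the knockdown, and PTPRC at 0.147 ± 0.0959 and 0.0279 ± 0.0128. Of 35 inflammatory cytokine and NF-kB target genes, 19 fell and 12 rose (median -0.21, adjusted p = 0.0283, and adjusted p = 0.119 with an estimated correlation), and the median ranged from -0.36 to -0.11 over the alternatives. CXCL8, a neutrophil attractant, fell from 179 ± 6.21 to 46.5 ± 1.22 FPKM and IL1B from 56.4 ± 1.46 to 11.6 ± 0.414, while TNFAIP2 rose from 452 ± 15.7 to 1125 ± 23.0. Of 16 IL-36, antimicrobial peptide and alarmin genes, 7 rose and 6 fell (adjusted p = 0.998), with S100A9 up from 131 ± 3.03 to 327 ± 4.37 FPKM.

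Sterol genes were lower. Of 24 cholesterol synthesis genes, 23 fell and 1 rose, with a median log2 change of -0.93 (camera adjusted p = 1.54e-10), and this call held with an estimated correlation (adjusted p = 0.0341). IDI1, an isomerase of the pathway, fell from 220.1 ± 10.5 to 59.0 ± 2.47 FPKM and HMGCS1, an early enzyme of the pathway, from 371 ± 11.8 to 114 ± 7.49. Of 36 lysosome and endosome genes, 19 fell and 10 rose (adjusted p = 0.0124, and adjusted p = 0.179 with an estimated correlation), with the lysosomal lipase LIPA down from 318 ± 13.1 to 131 ± 4.35 FPKM. Of 25 p53 target genes, 14 fell and 8 rose (adjusted p = 0.0382, and adjusted p = 0.312 with an estimated correlation). This call held in 13 of 17 alternatives, with a highest adjusted p of 0.0670. Among these genes, GADD45A fell from 462 ± 22.3 to 35.6 ± 1.61 FPKM and the cell cycle inhibitor CDKN1A from 459 ± 10.9 to 133 ± 1.62. Of 44 cytosolic ribosomal proteins, 29 fell and 3 rose (median -0.13, adjusted p = 0.00135, and adjusted p = 0.424 with an estimated correlation), with RPLP1 at 2098 ± 40.4 and 1671 ± 32.9 FPKM. With upper-quartile scaling 38 ribosomal genes fell and 1 rose (median -0.24), and with quantile normalization 15 fell and 10 rose (median -0.03), which ended the call (adjusted p = 0.351, with a range of 1.18e-05 to 0.351 over its alternatives).

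The remaining lists did not pass as groups. The unfolded protein and integrated stress response list had 12 genes that rose and 11 that fell (adjusted p = 0.334), with DDIT3, a stress transcription factor, down from 38.1 ± 3.44 to 4.18 ± 0.240 FPKM. The hypoxia and glycolysis list had 12 that rose and 11 that fell (adjusted p = 0.827), with VEGFA down from 202 ± 5.77 to 78.4 ± 4.30 FPKM. The NRF2 list had 11 that rose and 7 that fell (adjusted p = 0.827), with AKR1B10 up from 1.52 ± 0.348 to 8.37 ± 0.364 FPKM. In the heat shock list 8 rose and 5 fell (adjusted p = 0.766), and HSPA1A fell from 72.8 ± 0.800 to 52.0 ± 1.29 FPKM. In the PI3K-AKT and FOXO list 7 rose and 9 fell (adjusted p = 0.132), and it passed in 2 of 17 alternatives (lowest adjusted p = 0.0439). IRS1, an insulin receptor adaptor, fell from 45.9 ± 2.88 to 11.2 ± 0.909 FPKM. Among the 6 gamma-secretase subunits 2 rose and 3 fell (adjusted p = 0.497). In several of these lists the median, mean and test differed in sign, as for hypoxia and glycolysis, with a median of 0.05, a mean of -0.05 and a downward test.

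**Figure D3:**
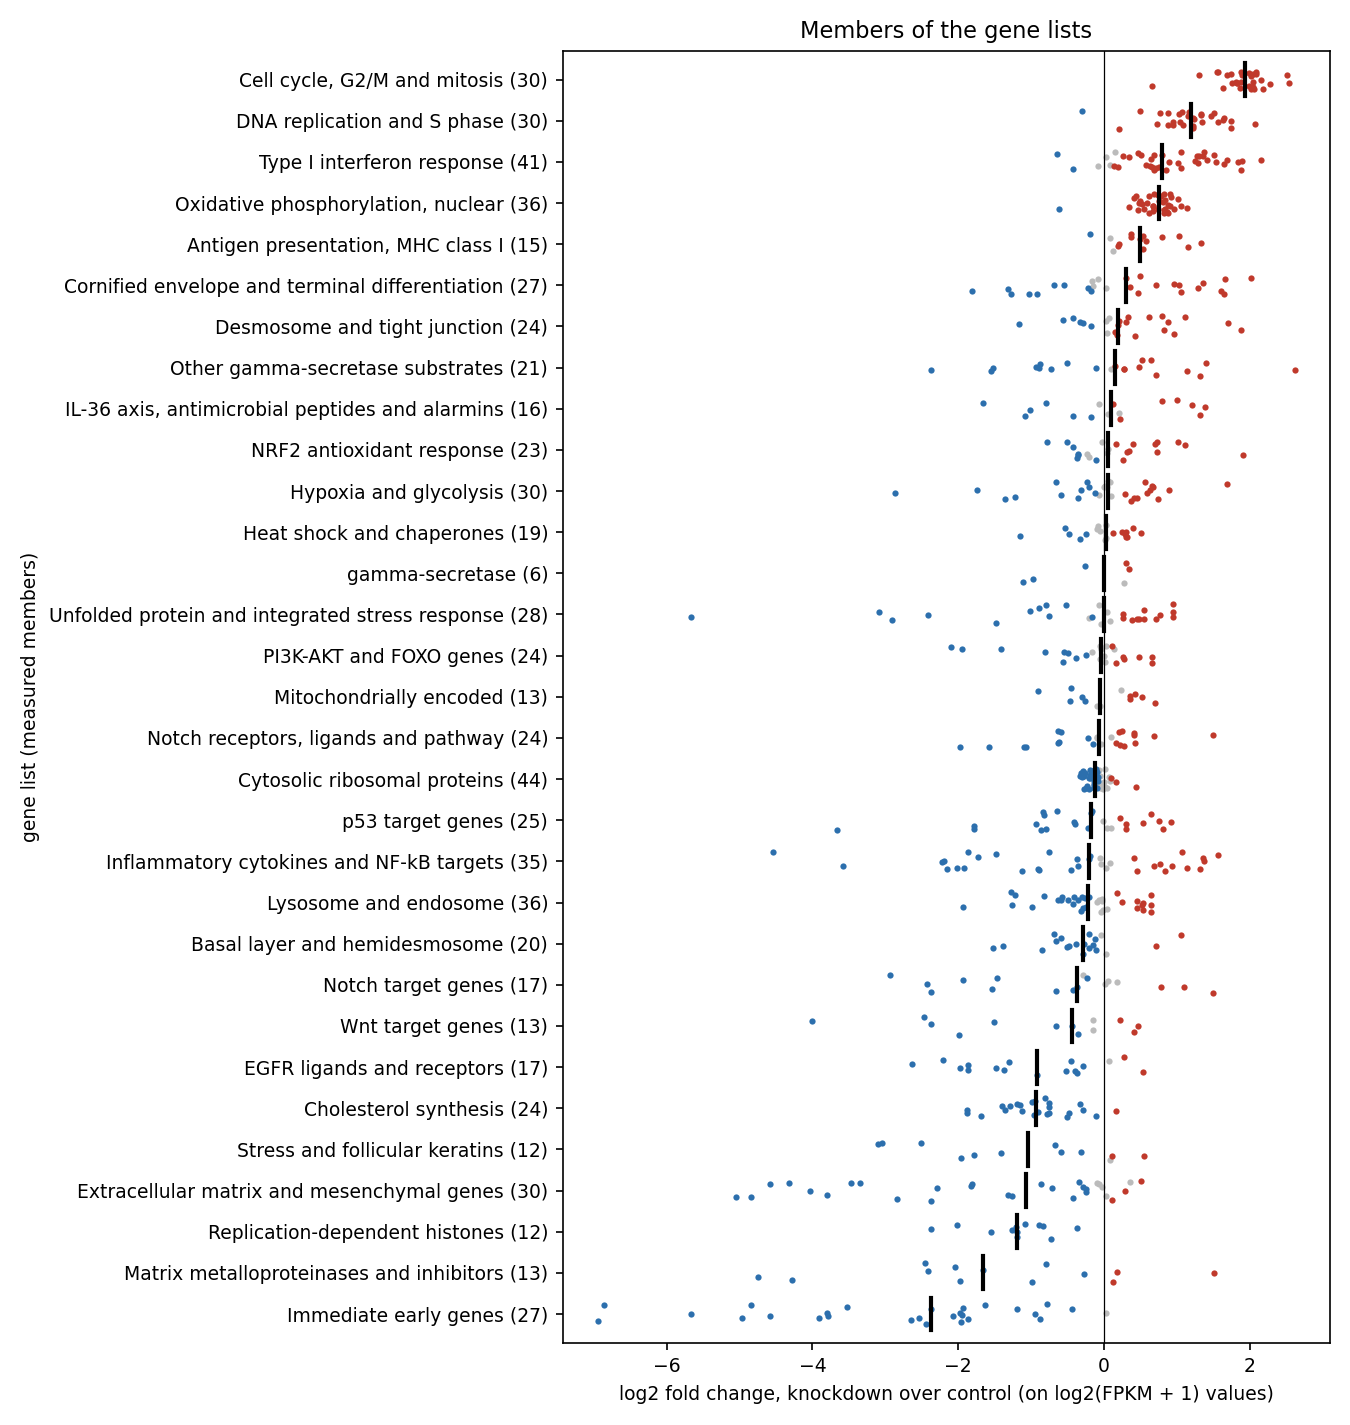
Log2 fold change of knockdown over control (horizontal axis) of every measured member (points) of the 31 tested gene lists (vertical axis, with the number measured), in red where a member rose, blue where it fell and grey where it did not pass. Black bars are list medians, which run from -2.37 for immediate early genes to 1.94 for G2/M and mitosis genes.

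Markers of other cell types were too few above the filter for a list test. Of fibroblast markers above the filter, COL1A1 fell from 31.1 ± 1.35 to 17.0 ± 0.248 FPKM and MFAP5 from 2.20 ± 0.385 to 0.399 ± 0.107, while FBLN1 rose from 35.1 ± 2.32 to 69.3 ± 1.45. Without a filter, more fibroblast markers fell than rose, as given above with the matrix genes. Of melanocyte markers, MITF fell from 4.68 ± 0.528 to 1.87 ± 0.344 FPKM and PMEL rose from 2.00 ± 0.155 to 2.89 ± 0.263. Of endothelial markers, VWF rose from 2.99 ± 0.349 to 6.95 ± 0.616 FPKM, EGFL7 rose from 2.69 ± 0.605 to 4.34 ± 0.587 and CDH5 fell from 8.37 ± 0.186 to 4.24 ± 0.880. Adjusted over the list alone, the counts of members that rose and fell were those given above, except for 36 interferon-stimulated and 13 MHC class I genes that rose and 6 heat shock genes that fell. Of the 19 lists that passed with the preset correlation, 2 passed with an estimated one, the matrix and cholesterol lists. Some lost calls had estimates below the preset 0.01, namely EGFR (-0.017), metalloproteinases (-0.045), MHC class I (-0.024) and inflammatory genes (-0.013). Correlation between genes thus did not end those calls. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries, which also raises p. By fry, 28 of the 31 lists moved on balance one way, which does not compare them with other genes.

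The authors' deposited table listed 9840 genes, 4835 higher and 5005 lower in the knockdown. Of these, 8415 were tested here, and 8193 passed with the same sign, 222 did not pass and 0 passed with the opposite sign. Another 1564 genes passed here and were not in the authors' deposited table. Log2 fold changes from both sources had a Spearman rho of 0.994 across 8408 genes, which come from the same reads and are not independent. Of the 1445 genes changed at least 2-fold here, 1408 were also at least 2-fold in the authors' deposited table with the same sign. That table held 3360 genes changed at least 2-fold, 1172 higher and 2188 lower, so most of them were not 2-fold here. The limits are not alike, since the authors' is a ratio of mean read counts and the scale here understates changes at low FPKM. Of all genes the authors listed, 1425 were below the filter here. In the authors' deposited table NCSTN had a log2 fold change of -1.21.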

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

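There were 17 alternatives, of which the recovered reads with voom and the length and GC correction were added after the data were seen. The count of changed genes ranged within 1.5 times of 9757, from 7698 with a mean FPKM of at least 5 to 10814 with no filter. These were 76.6% of 10054 and 34.7% of 31166 tested genes, against 71.7% in the main fit, so the share called depends on the filter. Leaving out each replicate in turn gave 9133 to 9530 genes. The count of at least 2-fold changes rose from 1445 to 2022 with a pseudocount of 0.1, to 2106 with 0.01 and to 2100 with recovered reads. NCSTN stayed lower and past the threshold in all 17, with log2 changes of -1.24 to -1.09. Recovered reads gave 4798 genes higher and 4866 lower, close to the split with upper-quartile scaling, and moved the median log2 change of all tested genes from 0.095 to 0. The median-ratio factors used with them centre that median near 0 by design, so neither that shift nor the near-even split is separate evidence. Of 148 genes that the naming rule takes, 145 passed under every alternative in which they were tested and none reversed. The exceptions were PSENEN, APH1B and ITGAM. Most of these genes were picked for large changes or small adjusted p, so their passing again says little about the rest. Of all 9757 calls, 8636 were shared with the same sign under upper-quartile scaling, 8695 with recovered reads and 8536 after the length and GC correction.

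The inflammatory list missed the threshold with no filter (adjusted p = 0.0859) and with upper-quartile scaling (adjusted p = 0.0773), over a range of 0.00307 to 0.0859. The p53 list passed in 13 of 17 alternatives, and the PI3K-AKT and FOXO list in 2. The cause of these changes was not tested. With the replicate number as a block (replicate block), 10003 genes changed. Same-numbered libraries had correlations of deviations of -0.001, 0.028 and 0.152, and not every library matched its own number best, so the numbers were not taken to pair the libraries. Planned tests on raw counts were not run. At 20319637 to 23291081 reads, APH1B rested on a mean of 40.3 reads and DLL4 on 3.0 reads per knockdown library, so counting error weighs on these values. The Notch ligand DLL4 had a mean of 138.3 reads in the control and was lower and past the threshold in all 16 of its alternatives. For DLL4 the uncertainty thus lies in the size of the fall, with log2 changes of -5.66 to -1.77.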

Other observations

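Other gene groups, listed after the data were seen, also held many changed members, given as counts with no list test. Since 71.7% of all tested genes passed, a large share of changed members is in itself no mark of a group. Of 21 measured genes of the actin cytoskeleton and its regulator SRF, 20 fell and 0 rose, with a median log2 change of -0.98. TAGLN, an actin-binding protein, fell from 36.5 to 2.41 FPKM and TPM1, a tropomyosin, from 232 to 46.8. Control library 2 stood apart on the smooth muscle actin ACTG2, at 4.08 FPKM against 0.0379 and 0.0848 in the other control libraries and 0 in each knockdown library, and without it 20 genes still fell and 0 rose. Of 7 measured MHC class II genes, 6 rose and 0 fell, among them CIITA, CD74 and HLA-DRA, which had been seen to rise before the list was written, with HLA-DRB1 up from 2.10 to 7.93 FPKM and HLA-DQB1 at 21.3 FPKM in both groups. Of 21 measured YAP and TEAD targets, 15 fell and 2 rose, and the 17 whose values had not been seen when the list was written had a median of -0.609. Of 9 type I and III interferon genes, 1 was above the filter, IFNE, at 1.21 FPKM in the control and 1.08 in the knockdown, and it did not pass. IFNB1 was at 0.0195 FPKM in the control and 0 in the knockdown.

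Of the tests given here, those of leukocyte genes, of S phase, of sense intronic genes alone and without control library 2 for the later lists were chosen after the results they bear on were seen, and the length and GC correction was added after the data were seen. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the real 9757, namely the real one. The highest other gave 0 by limma (21 to 87 genes at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05. Every other split also puts libraries of both groups on each side. The group difference then adds to the spread, so few calls were bound to result and the 0 says little about chance. Overlapping windows of 100 neighbouring genes were scanned for regional shifts, as a difference in chromosome copy number between the cultures could give. The largest absolute median relative to all genes was 0.289, on chromosome 4 from 127781821 to 184694618 (GRCh38). Of 449 windows, 6 exceeded 0.22, the 95th percentile of the largest value in 1000 shuffles of gene order. All of these lay on chromosomes 4 and 9, where windows share genes. The scan could not tell whether copy number differed.

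The fall of the immediate early genes was set against 3 technical explanations. Under upper-quartile, quantile and TPM scaling the list median was at most -2.38, and after removal of length and GC trends it was -2.389. These steps changed the median of all tested genes little, from 0.095 to between -0.001 and 0.097. They were thus bound to leave a fall of this size. Depth differences and smooth length and GC trends are too small to be its whole cause, and no other technical cause is tested by these steps. A general excess of unspliced or short-lived RNA in the control libraries was predicted to lower intronic and antisense transcripts too. The 662 such genes had a median log2 change of -0.007, with quartiles of -0.443 and 0.371. Antisense reads cannot be told from sense reads here, but the 73 sense intronic genes alone had a median of -0.102 and a lower quartile of -0.495, far above the list median. The stability of these transcripts was not measured. Their values thus bear on unspliced RNA and do not test an excess of short-lived mRNA. A difference in feeding, density or handling at harvest may still be the source, since such conditions are confounded with the groups and were not tested, and an effect of NCSTN loss or an off-target effect of the shRNA stays open as a hypothesis beside it.

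The rise of the interferon-stimulated genes kept a median of 0.793 after removal of length and GC trends. Immune cells in the knockdown cultures were tested with 8 leukocyte genes, of which 1, ITGAM, had a knockdown mean of at least 1 FPKM. That was short of the 4 set for such cells and above the 0 set without them, limits written after the rise was seen. Of immune cell markers outside the 8, CD14, CD74 and HLA-DRA stood above 1 FPKM in the knockdown and others, such as CSF1R, below it. The count thus depends on the choice of genes and does not decide. PTPRC, present in all leukocytes, was at 0.147 FPKM in the control and 0.0279 in the knockdown. A difference between the viral preparations could also raise these genes and was not tested, so an effect of the knockdown is 1 hypothesis among those left open.

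The 12 measured histone transcripts, of 33 listed, fell while the DNA replication genes rose. That 1 of 30 DNA replication genes fell is part of this pattern, so it does not test whether fewer cells were in S phase. A candidate explanation is more RNA without a poly(A) tail in the control libraries, since 8 other such genes had a median log2 change of -0.427, with quartiles of -0.731 and -0.139. Of these, 4 fell and 1, RN7SL1, rose from 553 to 1420 FPKM, and with 2 further genes of the misc_RNA class, which both rose, the median of 10 was -0.241, so the explanation stays open. A biological difference between the groups in histone mRNA was not tested apart from this, and neither was whether the measured histone transcripts carry a poly(A) tail.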
